A study of Mus musculus with 3 samples.

How the data were processed

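RNA of skeletal muscle from ICR mice was extracted with Trizol, and 500 ng of total RNA per sample went into Lexogen QuantSeq 3' libraries read on an Illumina NextSeq 500, per the labels' protocols and the series description. In a 3' library the number of reads from a transcript does not grow with its length. Such a library measures only the annotated or unannotated 3' end that the reads reach. The submitters' processing notes name Bowtie2, edgeR and the mouse build mm10, without versions or the role of each. The counter, the gene annotation, strand handling and filters are not given in the sources used here.

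Each of the 3 deposited files holds 1 library, with a log2 value to 3 decimals for each of 24481 gene rows, from 0 to 19.83. The rows carry 24421 symbols, because 43 symbols stand on several rows, 103 rows in all. Per the file headers a column holds only a sample code, so the unit of the deposited log2 values was worked out from the values. Low values, raised back to the linear scale, bunch at whole multiples of a step that is the same for all genes of a library, as a library-size-adjusted read count would. The step was 0.937 in the control, 1.20 in the exercise control and 0.762 with SQH. Of linear values up to 9, 99.8%, 94.1% and 82.3% lay within 0.2 step of a whole multiple. The bunches are too wide to give exact reads, so no count model was fitted and reads are approximate. A value of 0 stands for no read or 1 read in the control and SQH libraries and for no read in the exercise control. Dividing each library's linear sum by its step gives 10.8, 8.07 and 12.5 M reads. Ribosomal precursor RNA (Rn45s) made up 9.19%, 9.06% and 7.25% of the linear sums.

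Groups come from the sample titles, and there is 1 library per group. The comparisons were exercise control against control, exercise plus SQH against exercise control, and exercise plus SQH against control. The test was planned for read counts or, if the files held normalized values, as a size rule, and the latter applied. A gene was called when its log2 values differed by at least 1 (2-fold) and its mean linear value over the 3 libraries was at or above the median of the 15714 rows not at 0 in all libraries (66.5), which left 7857 rows. No p-value was computed, since there is no replicate. The standard error beside a difference is that of the ratio of 2 Poisson counts at the approximate reads. It ranges from 0.025 to 1.43 among the genes with the largest differences, and covers counting only. The deeper SQH library measures low genes more precisely than the exercise control, which is the shallowest.

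Gene lists (33, of which 22 are pathways and 11 are cell types or sex) were fixed before the data were examined. Of their 790 genes 754 were found and 574 passed the expression minimum. For the 28 lists with at least 5 such members, the median difference was placed among 10000 random lists of the same size drawn from 20 expression bins, and the central 95% of the random medians is called the random range. Of the 84 medians so placed, 27 lay outside it. The 84 are not separate results, because the comparisons share libraries and some lists share genes. Members of a list may also vary together, which the random lists do not reproduce. Genes to be named were chosen by a rule fixed at the same time. For each comparison these are the 12 higher and 12 lower called genes with the largest difference, and from each list up to 4 called members with the largest difference or, where no member was called, up to 2. Genes known only by a clone or model number, pseudogenes and small RNA genes were counted and not named, and neither were symbols on several rows. Genes with a value of 0 in either library were not ranked, and no fold was computed for them, but the 2 such rows past the minimum (Prss22 and Tecrl) are in the counts. Partner genes named for an overlap, and the other subunits of succinate dehydrogenase, were chosen after their values were seen. The values of 1 gene that the rule names are not reported here. Positions are those of GENCODE M21 for GRCm38, the assembly called mm10, in which 95.7% of the symbols were found. Exonic overlap was taken from the same annotation.

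Because comparisons share libraries, 100 sets of 3 libraries with no group effect were simulated. Their noise was drawn from the differences between the SQH and control libraries, divided evenly between both, so real differences between those libraries count as noise there. The call rule was tested on simulated data with 200 changed genes, made from the mean of the control and SQH libraries with counting noise alone. Those data hold no noise between animals or library preparations. Their share of called unchanged genes is therefore no rate of false calls for the real data. In exercise control against control, with 7530 genes passing the minimum, 60% of genes changed 2-fold, 90% of those changed 4-fold and 96% of those changed 8-fold were called, and 0 of 7342 unchanged genes were. In exercise plus SQH against exercise control (7531 genes) these shares were 46%, 94% and 86%, and in exercise plus SQH against control (7537 genes) 40%, 92% and 82%. A 2-fold change sits on the threshold, and some genes made lower fell under the expression minimum. In the last comparison 100 of 100 simulated lists of 20 genes raised by 0.5 lay outside the random range, against 8 of 100 unchanged lists.

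Alternatives were centring, quantile normalization, other expression minimums, 1.5-fold and 3-fold thresholds, a prior count of 5, an assumed biological coefficient of variation of 0.2 and thinning of the approximate reads to 8.07 M. Alternatives chosen after seeing the data were a counting interval, leaving out rows that overlap another tested gene, and leaving out members of the fibre type, nerve, tendon and adipocyte lists. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.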

Results

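Messenger RNA was profiled in skeletal muscle of ICR mice, an outbred stock, at postnatal day 42. The title of the study names a leaf extract of Sasa quelpaertensis, a dwarf bamboo, and fatigue, and the sample labels name a control, an exercise control and exercise with a treatment given as SQH. There were 3 libraries, 1 per group, and the labels do not say whether a library holds muscle of a single animal or of several. The labels also give no name of the muscle, no exercise protocol and no SQH dose. Each library was made by 3' end sequencing, in which reads come from the end of the transcript next to the poly(A) tail. The deposited values were log2 levels for 24481 gene rows, of which 15714 lay above 0 in at least 1 library. The libraries held about 10.8 M reads in the control, 8.07 M in the exercise control and 12.5 M with SQH, as estimated from the spacing of their low values. With no replicates, no difference below has a replicate error or a p-value. A gene was called higher or lower by size alone, at a difference of 2-fold or more (1 on the log2 scale), among the 7857 rows with a mean linear value of at least 66.5. The ± value beside a difference is the approximate standard error of counting reads, which covers neither animals nor library preparation. All 3 libraries carried Y-linked transcripts, with Ddx3y between 10.92 and 11.26 and Uty between 8.41 and 8.66. Eif2s3y stood at 6.69, 7.81 and 7.59 in control, exercise control and exercise plus SQH, and Kdm5d at 5.97, 5.54 and 5.43. Xist, the RNA that coats the inactive X, was listed at 0, 0.32 and 0, and the identical values of Tsix on the other strand cannot be told from it.

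The exercise control was set against the control to ask how muscle of the exercise control group differed from that of the control group. The transcripts of slow-twitch fibres were far lower in the exercise control library. Of the 16 slow-fibre contractile genes, 14 were called lower, and the list median difference was -3.45. Sln, which encodes sarcolipin, an inhibitor of the sarcoplasmic calcium pump, was lower by the largest amount, at 11.43 in the control and 5.74 in the exercise control (-5.69 ± 0.22). The slow troponin genes Tnni1 (-4.07 ± 0.05) and Tnnt1 (-4.06 ± 0.03), the slow tropomyosin gene Tpm3 (-4.02 ± 0.03) and the slow myosin gene Myh7 (-3.92 ± 0.04) shifted by similar amounts. Myh6, the alpha myosin heavy chain gene beside Myh7, differed by -4.35 ± 0.07. Mhrt, a non-coding RNA gene of the opposite strand, shares 484 exonic bases with Myh7 and differed by -4.53 ± 0.10, so its reads may not be its own. In the mouse genome build GRCm38 these 3 genes lie together on chromosome 14, Myh6 from 54941921 to 54966927, Mhrt from 54968678 to 54974349 and Myh7 from 54970684 to 54994626. The fast-fibre contractile genes lay slightly above the control, with a list median of 0.42 and 16 of 18 members above 0, but only Myoz1 was called higher (1.01 ± 0.02).

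**Figure D1:**
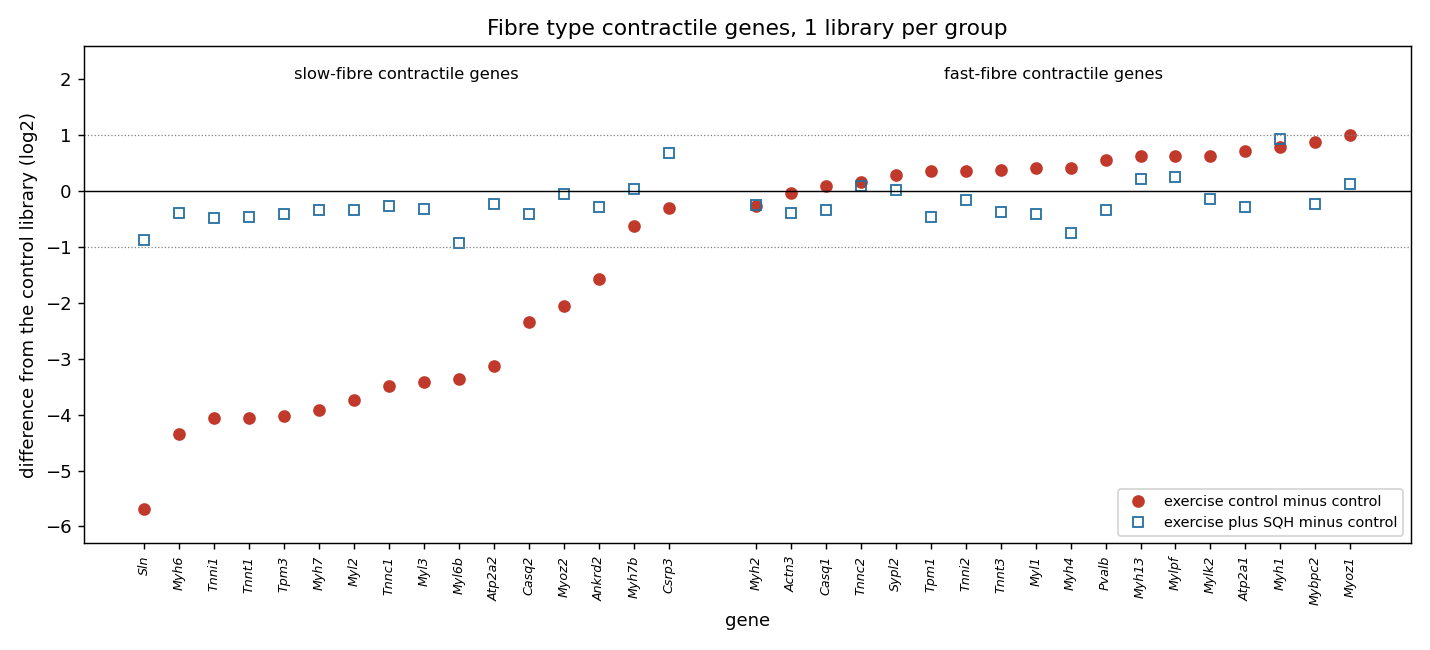
Difference from the control library on the log2 scale (vertical axis) for the tested members of the slow-fibre and fast-fibre contractile lists (horizontal axis). Filled circles stand for the exercise control and open squares for exercise plus SQH, 1 library each, with dotted lines at 2-fold. Slow-fibre genes such as Sln lie far lower in the exercise control (-5.69) than with SQH (-0.87), and Myoz1 (1.01) is the only fast-fibre gene past 2-fold.

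Genes of glycolysis and glycogen metabolism were higher in the exercise control library, with a list median of 0.67, 25 of 28 tested members above 0 and 6 called higher. Among them were Pfkfb3 (1.90 ± 0.08), whose enzyme makes the activator of phosphofructokinase, Fbp2 (1.63 ± 0.12), the muscle fructose bisphosphatase, and Phkb (1.23 ± 0.06), a subunit of phosphorylase kinase. Slc16a3, the lactate exporter MCT4, was also higher (1.37 ± 0.02) and Ldhb, the lactate dehydrogenase subunit of oxidative tissue, lower (-1.06 ± 0.06). Genes of fatty acid uptake and oxidation were lower as a list, with a median of -0.32 and 25 of 29 below 0, and Etfa (-1.41 ± 0.12) and Fabp3 (-1.11 ± 0.02) were called. The tricarboxylic acid cycle list had a median of -0.26, inside its random range, with 2 called members. These were Idh2 (-1.49 ± 0.03) and Sdhd (-3.82 ± 0.21), a membrane subunit of succinate dehydrogenase. The 77 nuclear-encoded genes of oxidative phosphorylation had a median of 0.07 (0.14 after centring and 0.15 after quantile normalization), and Sdhd was the only member called. These shifts were measured in the library whose slow-fibre median stood at -3.45.

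The metallothionein genes Mt1 and Mt2, which encode zinc-binding proteins induced by metals and glucocorticoids, had the largest positive differences of the named genes in the exercise control. Mt2 stood at 8.10 in the control and 11.74 in the exercise control (3.64 ± 0.09), and Mt1 at 8.16 and 11.05 (2.89 ± 0.09). They lie side by side on chromosome 8 (Mt2 from 94172664 to 94173568, Mt1 from 94179082 to 94180327). Of the 22 glucocorticoid-responsive genes, 4 were higher and 1 lower. Besides the metallothioneins, the higher ones included Glul, glutamine synthetase (1.48 ± 0.04), and Tsc22d3, which encodes GILZ (1.28 ± 0.03). The list median was 0.07, inside the random range. Genes of muscle atrophy and autophagy had a median of 0.35 (-0.02 to 0.57 on resampling the members), with Gadd45a (1.33 ± 0.15) and the ubiquitin ligase gene Trim63 (1.06 ± 0.04) higher and Foxo6 (-1.09 ± 0.20) lower. In the heat shock and unfolded protein list, with a median of -0.29 (-0.67 to 0.06 on resampling), Hspa1a (-2.57 ± 0.27), Hspb7 (-1.34 ± 0.06) and Cryab (-1.14 ± 0.03) were lower, while Chac1, a glutathione-degrading enzyme induced by endoplasmic reticulum stress, was higher (2.71 ± 0.20). Of 26 immediate early genes, 3 were higher and 3 lower. Nr4a3 (2.02 ± 0.20), Nr4a2 (1.53 ± 0.28) and Maff (1.18 ± 0.27) lay above the control, whereas Cyr61, which encodes a secreted matrix-associated protein, was lower (-4.06 ± 0.17).

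Other named genes higher in the exercise control were Slc25a29, a mitochondrial carrier of basic amino acids (2.83 ± 0.25), the E-cadherin gene Cdh1 (2.64 ± 0.27), the interferon-induced Ifit3 (2.19 ± 0.25), the receptor gene Eda2r (2.17 ± 0.21), the transcription factor gene Runx1 (2.12 ± 0.35), the cytokine signalling inhibitor Cish (2.12 ± 0.15) and Tmem56 (2.04 ± 0.17). Ces5a (-6.06 ± 1.02), Sox18 (-5.88 ± 1.43), Paox (-5.25 ± 0.84) and Sbk3 (-3.90 ± 0.52) were nearly absent from that library, and their large standard errors reflect very few reads there. The clock output gene Dbp (-1.92 ± 0.15) and the clock repressor gene Nr1d1 (-1.39 ± 0.13) were lower. Each shares exonic bases with a neighbour on the opposite strand, Dbp with Sphk2 and Nr1d1 with Thra. The same holds for Cryab with Hspb2, Fabp3 with Zcchc17, Paox with Echs1 and Atp2a1 with Rabep2. In each of these pairs, part of the reads of either gene may belong to the other. Echs1 (0.04) and Zcchc17 (-0.14) did not shift with Paox and Fabp3, so reads of these neighbours would not produce the lower values of Paox and Fabp3. Against 10000 random lists of equal size matched on expression, the slow-fibre median lay below every random median, as a description of these 2 libraries.

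Markers of nerve moved with these changes. All 6 tested nerve and Schwann cell markers lay above the control and 5 were called higher, among them the myelin genes Ncmap (2.41 ± 0.20) and Mbp (1.85 ± 0.16) and the Schwann cell gene S100b (1.09 ± 0.18), for a list median of 1.47. Tendon markers had a median of 0.95, with a resampling range that included 0 (-0.43 to 1.496), and with Tnmd (1.59 ± 0.31), Fmod (1.496 ± 0.17) and Cilp2 (1.42 ± 0.11) higher and Scx (-1.18 ± 0.16) lower. Of 9 tested adipocyte markers 4 were lower, including Cidea (-1.68 ± 0.32) and Elovl3 (-1.57 ± 0.30), although the list median of -0.42 was inside its random range. The endothelial list (median -0.02), the fibroblast and matrix list (-0.01), the erythroid list (-0.09) and the smooth muscle and pericyte list (-0.31) stayed inside theirs. Single members of these lists that were called were Robo4 (-1.62 ± 0.27), Col1a1 (1.28 ± 0.04), Rgs5 (-1.49 ± 0.04) and Lmod1 (1.36 ± 0.12).

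In all, 232 genes were higher and 419 lower in the exercise control than in the control. With each library centred on its median these became 293 and 348, so the excess of lower genes depended in part on scaling. Neither count can be made without the exercise control library.

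Exercise plus SQH was set against the exercise control to ask what the treatment added in exercised muscle. The slow-fibre genes stood far higher in the SQH library, where 14 of 16 were called and the list median was 3.16. Sln (4.82 ± 0.22), Myh6 (3.96 ± 0.07), Tpm3 (3.62 ± 0.03) and Tnnt1 (3.61 ± 0.03) showed the widest gaps in the list. The fast-fibre list was lower, with a median of -0.63 (-0.42 after quantile normalization) and 16 of 18 members below 0. Myh4, the myosin heavy chain gene of the fastest fibres (-1.16 ± 0.01), Mybpc2 (-1.12 ± 0.02) and Atp2a1, the fast calcium pump gene (-1.01 ± 0.01), were called. Glycolysis and glycogen genes were lower by a median of -0.50, with 4 of 28 called, including Fbp2 (-2.24 ± 0.13), Phkb (-1.45 ± 0.06) and Gpd1 (-1.10 ± 0.04). Genes of fatty acid uptake and oxidation were higher, with a median of 0.31 and 26 of 29 above 0. The called members were Pdk4 (1.96 ± 0.04), the kinase that shuts pyruvate dehydrogenase, Etfa (1.78 ± 0.12) and Fabp3 (1.24 ± 0.02). The tricarboxylic acid cycle list had a median of 0.26, with 15 of 23 members above 0, and Sdhd (4.74 ± 0.21) and Idh2 (1.16 ± 0.03) called higher. All of these lists shift in the direction opposite to that of the exercise control against the control, and the exercise control library enters both differences.

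Immediate early genes had a list median of 0.44 in the SQH library, with 16 of 26 members above 0 and 10 below, 4 called higher and 1 called lower. Among the higher were Cyr61 (4.43 ± 0.17), the stress-induced transcription factor gene Atf3 (2.75 ± 0.21) and Rrad (1.68 ± 0.10), and the lower gene was Gadd45g (-1.53 ± 0.10). Regeneration and denervation markers had a median of 0.52 (1.54 among the genes of highest expression), with the acetylcholine receptor gene Chrna1 (1.85 ± 0.09), the muscle regulatory factor gene Myog (1.59 ± 0.10), Xirp1 (1.54 ± 0.09) and Ankrd1 (1.52 ± 0.14) higher and no member lower. The heat shock and unfolded protein list was higher by 0.25, with Hspa1a (3.19 ± 0.26), Dnajb9 (1.66 ± 0.24) and Cryab (1.51 ± 0.03) higher and Chac1 (-1.52 ± 0.14) lower. The antioxidant list had a median of 0.24 with 17 of 26 members above 0. Its 4 members called higher included Mgst1 (1.45 ± 0.19), Mgst3 (1.42 ± 0.11) and the catalase gene Cat (1.12 ± 0.08). The 1 lower member was Gclm (-1.46 ± 0.18), a subunit of the enzyme that starts glutathione synthesis. Ppargc1a, which encodes the mitochondrial biogenesis coactivator PGC-1alpha, was higher (1.06 ± 0.04), but the list of biogenesis regulators had a median of 0.07 and no other called member. Resampling the members gave median ranges that included 0 for the immediate early list (-0.09 to 0.64), the tricarboxylic acid cycle list and the antioxidant list. Mstn, the myostatin gene, was lower (-1.52 ± 0.13), as was Il15 (-1.39 ± 0.25), and Metrnl was higher (1.42 ± 0.21). The exercise control library enters all differences in this paragraph. Against the control, that library was itself lower in Chrna1 (-1.51 ± 0.09) and higher in Gclm (1.09 ± 0.18) and Il15 (1.235 ± 0.25). Ankrd1, by contrast, was higher than the control in the exercise control library too (1.11 ± 0.20).

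Among the other named genes, the lowest in the SQH library relative to the exercise control was Mss51, a muscle mitochondrial gene (-3.15 ± 0.05), followed by Cish (-2.72 ± 0.16), Itpk1 (-2.17 ± 0.15), Cntf (-2.17 ± 0.23), Adamts20 (-2.09 ± 0.21), Cdh1 (-2.06 ± 0.21), Sc5d (-1.94 ± 0.19) and the carnosine synthase gene Carns1 (-1.82 ± 0.21). Cntf shares 847 exonic bases with Zfp91 on its own strand, and Zfp91 differed by -0.13. The highest included Sox18 (7.21 ± 1.42), Ces5a (5.34 ± 1.02), Paox (5.31 ± 0.84), Senp3 (4.58 ± 0.42) and Sbk3 (3.93 ± 0.52), all at 3.84 or less in the exercise control library.

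In the same comparison all 6 nerve and Schwann cell markers were called lower (median -1.55), with Ncmap at -2.05 ± 0.17 and Mbp at -1.79 ± 0.14. Adipocyte markers were higher, with a median of 1.09 and 5 of 9 called, including Cidea (2.39 ± 0.30), Dgat2 (1.32 ± 0.09) and Cfd (1.25 ± 0.20). The tendon list had a median of 0.06, with Cilp (1.09 ± 0.14) called. Of the fibroblast and matrix markers, Postn (1.43 ± 0.24), Fbn1 (1.08 ± 0.09) and Col6a1 (1.06 ± 0.23) were higher while the list median was -0.04. Altogether 446 genes were higher and 183 lower with SQH than in the exercise control. Centring gave 375 and 236 and quantile normalization 374 and 233, so the excess of higher genes also depended in part on scaling. Neither count can be made without the exercise control library, whose slow-fibre and nerve genes stand apart from both other libraries.

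**Figure D2:**
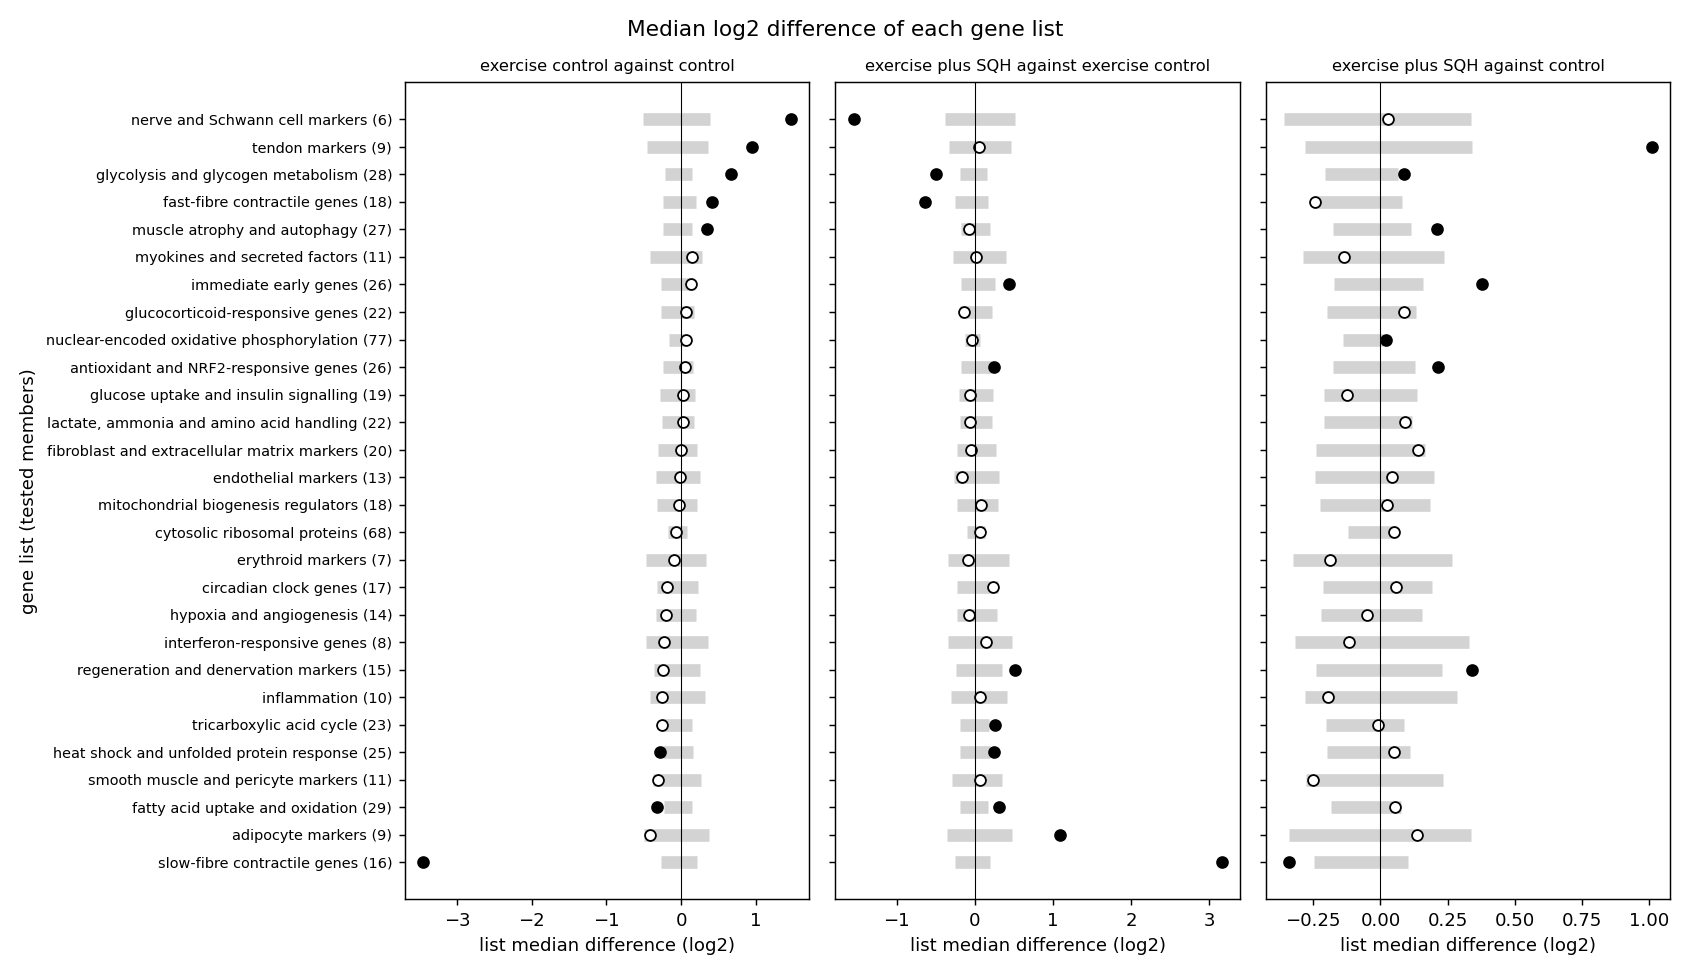
Median log2 difference (horizontal axis) of each gene list with at least 5 tested members (vertical axis, number of tested members in brackets) in the 3 comparisons, each with its own horizontal scale. Grey bars span the central 95% of 10000 random lists matched on expression, and filled circles lie outside that span. The slow-fibre list goes from -3.45 to 3.16 to -0.34 across the panels from left to right.

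Exercise plus SQH was also set against the control, the only comparison that leaves out the exercise control library. It had the fewest calls of the 3 comparisons, with 138 genes higher and 99 lower. The slow-fibre list was lower by much less than in the exercise control, with a median of -0.34, below its random range (-0.25 to 0.10), 14 of 16 members below 0 and no called member. Its lowest members were Myl6b (-0.92 ± 0.08) and Sln (-0.87 ± 0.04). The fast-fibre list had a median of -0.24 and no called member. Myh1, the gene of type IIX myosin, lay at 0.94 ± 0.01, and Myh4 at -0.74 ± 0.01. Nerve markers did not stand apart here (median 0.03, no called member), and neither did adipocyte markers (median 0.14), of which Cfd was higher (1.22 ± 0.18) and Thrsp lower (-1.71 ± 0.12).

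Metallothionein genes were again among the highest, with Mt2 at 3.60 ± 0.09 and Mt1 at 2.66 ± 0.09 above the control. Immediate early genes had a median of 0.38, with 6 of 26 higher and 1 lower. Nr4a3, an orphan nuclear receptor gene (2.58 ± 0.18), Maff (1.95 ± 0.24) and Atf3 (1.94 ± 0.15) were higher and Gadd45g was lower (-2.12 ± 0.09). Regeneration and denervation markers had a median of 0.34, with 5 of 15 higher, among them the stretch-responsive Ankrd1 (2.62 ± 0.17), Runx1 (2.33 ± 0.33) and the muscle regulatory factor gene Myf6 (1.16 ± 0.15). Ppargc1a was higher (1.65 ± 0.04), from 10.75 in the control and 11.35 in the exercise control to 12.41 with SQH, while the list of biogenesis regulators had a median of 0.02. Pdk4 was higher (1.58 ± 0.03) and so was Pfkfb3 (2.40 ± 0.07), in metabolic lists whose medians were 0.05 for fatty acids and 0.09 for glycolysis (0.17 after quantile normalization). The oxidative phosphorylation median was 0.02 (0.07 after quantile normalization), just above a random range that ended at 0.01, with Atp5g1 called higher (1.08 ± 0.04), and the tricarboxylic acid cycle median was -0.01. Antioxidant genes had a median of 0.21, which fell to 0.07 among the genes of highest expression. On resampling the members, the median ranges of the antioxidant (-0.01 to 0.46), glycolysis and oxidative phosphorylation lists included 0. Srxn1, which encodes sulfiredoxin (1.26 ± 0.07), and Mgst3 (1.16 ± 0.10) were higher, whereas the NRF2 target Nqo1 was lower (-1.10 ± 0.17). Muscle atrophy and autophagy genes had a median of 0.21, with Gadd45a (1.25 ± 0.14) and Gabarapl1 (1.20 ± 0.05) called.

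Further genes above the control in the SQH library were the neurogranin gene Nrgn (2.95 ± 0.33), Mustn1 (2.59 ± 0.08), the synaptic vesicle gene Sv2b (2.44 ± 0.15), Eda2r (2.18 ± 0.21), Mybph, which encodes a myosin-binding protein (2.44 ± 0.14), and the adenosine receptor gene Adora1 (2.45 ± 0.14). Mybph (chromosome 1, 134193448 to 134201232) and Adora1 (134199223 to 134235431) lie on opposite strands and share 1162 exonic bases. In control, exercise control and exercise plus SQH, Mybph stood at 6.89, 6.62 and 9.32 and Adora1 at 6.90, 6.62 and 9.35, so reads of the pair cannot be told apart. Lower genes included Ccdc36 (-2.75 ± 0.04), Kif3a (-2.59 ± 0.05), Timm22 (-2.39 ± 0.04), the cardiac actin gene Actc1 (-2.39 ± 0.07), the mitochondrial carrier gene Slc25a25 (-2.33 ± 0.25), the potassium channel gene Kcna5 (-2.30 ± 0.27), Gdap1 (-1.84 ± 0.23) and Arrdc2 (-1.81 ± 0.19). Amd1 (-1.92 ± 0.04) and Amd2 (-1.89 ± 0.03), near-identical genes of adenosylmethionine decarboxylase in polyamine synthesis, were also lower and may share reads. Ccdc36, Kif3a and Timm22 took the same order across the libraries as Amd1 and Amd2, and whether their reads are their own was not examined. Tendon markers had a median of 1.01 in this comparison, with a resampling range of -0.60 to 1.59, 6 of 9 above 0 and 5 called higher, including Tnmd (1.74 ± 0.29), Cilp (1.59 ± 0.14), Fmod (1.19 ± 0.17) and Cilp2 (1.19 ± 0.10). Rgs5, a pericyte gene, was lower (-1.62 ± 0.03), and the fibroblast gene Postn was higher (1.56 ± 0.22).

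The medians in this paragraph stayed inside their random ranges. For exercise control against control, exercise plus SQH against exercise control and exercise plus SQH against control, in that order, the median of the 17 circadian clock genes was -0.20, 0.23 and 0.06. The 19 genes of glucose uptake and insulin signalling had medians of 0.03, -0.07 and -0.13, with Tbc1d1, a regulator of glucose transporter traffic, above the control in both exercised libraries (1.89 ± 0.13 and 1.31 ± 0.13). Genes of lactate, ammonia and amino acid handling gave 0.02, -0.06 and 0.09, and glucocorticoid-responsive genes gave -0.13 and 0.09 in the comparisons with SQH. Inflammation genes gave -0.26, 0.06 and -0.19, with no called member among 10. The interferon-responsive list gave -0.23, 0.15 and -0.12, the hypoxia and angiogenesis list -0.20, -0.07 and -0.05, and the myokine list 0.14, 0.02 and -0.13. The 68 tested cytosolic ribosomal protein genes gave -0.07, 0.07 and 0.05. In the first comparison the biogenesis regulators had a median of -0.02, with Esrrg called lower (-1.08 ± 0.15), the regeneration and denervation markers -0.24 and the antioxidant genes 0.05. Endothelial markers gave -0.16 and 0.04 with SQH against the exercise control and the control, erythroid markers -0.08 and -0.19, and smooth muscle and pericyte markers 0.07 and -0.25. The fibroblast and matrix median was 0.14 with SQH against the control. Among immune cell markers only C1qa was tested, at 7.51 in the control, 7.60 in the exercise control and 8.28 with SQH, and no lymphocyte marker reached the expression minimum. Krt10, the only tested epidermis marker, stood at 6.64, 6.64 and 6.67. Of the 26 listed genes of the mitochondrial genome, 0 were found among the deposited gene rows under the listed symbols, so they could not be analysed.

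Genes shared by both exercised libraries were counted against the control. There were 51 genes higher in both and 20 lower in both, and apart from Mt1 and Mt2 the higher ones included Nr4a3, Pfkfb3, Runx1, Eda2r, Mustn1 and the tendon markers Tnmd, Fmod and Cilp2, and the lower ones Actc1, Rgs5 and Thrsp. Independent lists of these sizes would share 4.07 and 5.28. Because the control library enters both differences, 3 simulated libraries with no group effect shared 30.1 and 30.0, although only 226 genes were called there in exercise control against control, where the data had 651. The simulated lists differ in length from those of the data, and their noise includes any real difference between the SQH and control libraries. The 51 and 20 shared genes therefore cannot be compared directly with the simulated numbers. Part of both may come from the control library itself. Across genes, which are not independent replicates, the 2 differences from the control correlated at r = 0.38 against 0.50 in the simulation, and their covariance was 0.109 against 0.097.

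**Figure D3:**
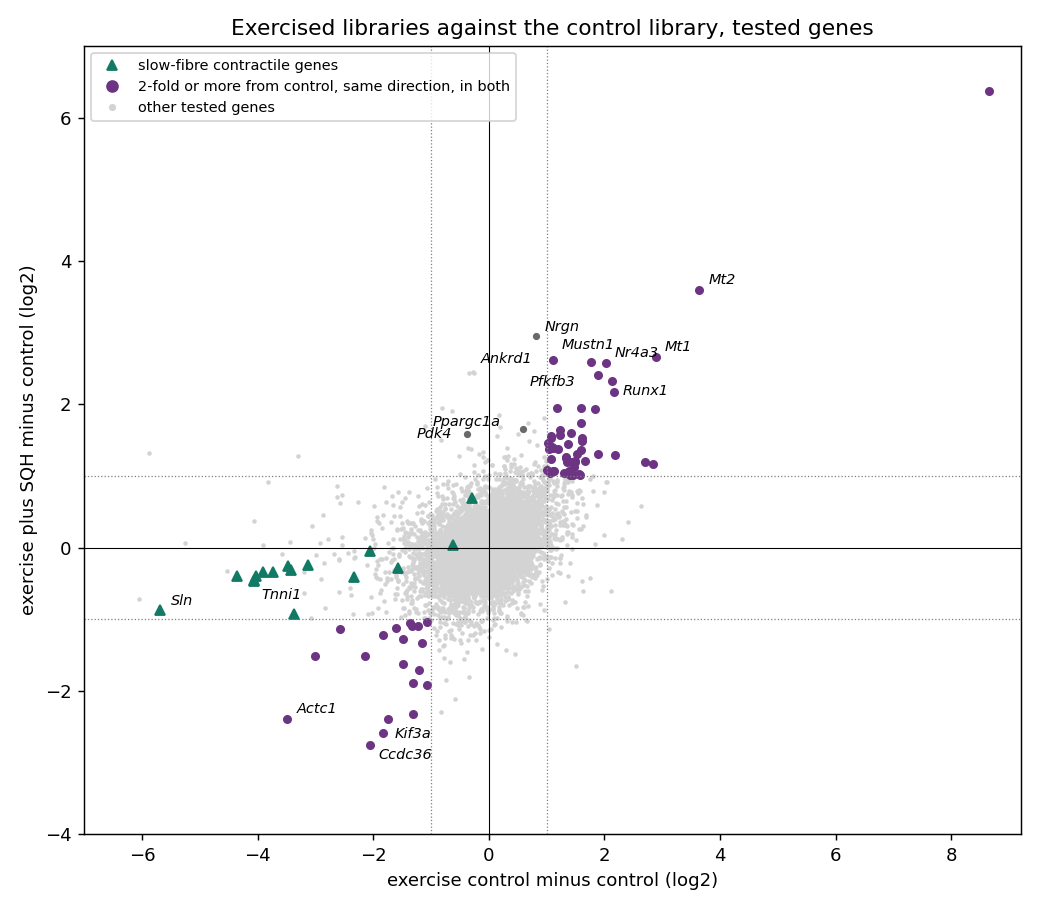
Log2 difference from the control of the exercise control (horizontal axis) and of exercise plus SQH (vertical axis) for the tested genes above 0 in all 3 libraries, 1 point per gene, with dotted lines at 2-fold. Purple points are the 51 genes higher and 20 genes lower in both exercised libraries, triangles are the slow-fibre contractile genes, and dark grey points are 3 labelled genes outside both sets. Mt2 lies at 3.64 and 3.60, while Sln lies at -5.69 and -0.87.

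The last comparison asked how far genes that differed in the exercise control lay from the control with SQH. On a scale where the control is 0 and the exercise control 1, the SQH library had a median position of 0.22 over the 651 called genes, with quartiles of -0.0009 and 0.49. Genes lower in the exercise control, which include the slow-fibre genes, had a median position of 0.12, and genes higher in it 0.41. In the simulated libraries with no group effect the median position was 0.51. Of the genes higher in the exercise control 75 were at least 2-fold lower with SQH than in the exercise control, and of the lower genes 261 were at least 2-fold higher. Independent lists would share 5.40 and 23.8, and the simulated libraries shared 28.7 and 30.0. The simulated lists were shorter, with 226 genes called against 651, so these overlaps cannot be compared directly. The correlation of the 2 differences was -0.76 against -0.50 in the simulation, and the covariance -0.307 against -0.097. These values hold for 1 library per group, and a library that stands apart for any reason would produce them.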

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

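All alternatives below were planned except the last group. No paired analysis was possible because each group has 1 library and no result comes from a test. Centring and quantile normalization kept every count of higher and lower genes within 1.5 times its value but moved the balance between them. The share of higher genes among those called went from 35.6% to 45.7% (centring) and 44.1% (quantile) in exercise control against control, and from 70.9% to 61.4% and 61.6% in exercise plus SQH against exercise control. In exercise plus SQH against control centring left it at 58.2% and quantile normalization gave 53.5%. Both scalings shifted the median of all tested genes by at most 0.07 in size. Thinning the reads to the smallest library also kept the counts within 1.5 times. The interval with an assumed biological coefficient of variation of 0.2 is narrower than the 2-fold threshold for all but genes with few reads, so it could end almost no call and is no test of stability.

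The counts of higher and lower genes depend on the minimum and the threshold by construction. Without an expression minimum they were 1841 and 2418 for exercise control against control, 2558 and 1638 for exercise plus SQH against exercise control, and 1872 and 1495 for exercise plus SQH against control. Among the 3929 rows of highest expression they were 75 and 158, 166 and 52, and 36 and 22 in the same order. At 1.5-fold they were 796 and 1216, 1159 and 729, and 582 and 500, and at 3-fold 42 and 125, 136 and 23, and 29 and 15. The median position of the SQH library between control and exercise control was 0.28 at 1.5-fold and 0.12 at 3-fold, and stayed inside the bootstrap range of its value (0.18 to 0.25) with centring and among those 3929 rows.

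Slow-fibre medians stayed inside their bootstrap ranges in all 12 alternative values, and no list outside its random range changed sign. Of the other list medians, 304 alternative values stayed inside and 8 moved. For named genes, 443 alternative values stayed within the counting interval and 41 moved, with no called gene changing sign. Among the alternatives chosen after seeing the data, the counting interval, which has the same limit, gave 231 and 418, 445 and 182, and 138 and 99 genes. Without rows overlapping another tested gene the counts were 207 and 360, 381 and 159, and 126 and 90. Leaving out members of the fibre type, nerve, tendon and adipocyte lists gave 223 and 400, 426 and 174, and 132 and 98. These lists hold few of the called genes, so leaving them out could change the counts little. It does not test whether the counts depend on the make-up of the tissue. What depth limits is the genes with few reads in the exercise control, such as Sox18, where the counting standard error is 1.43.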

Other observations

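The tests of strand handling and neighbouring genes were set out before their results were seen, and the other tests here after. Some genes stood at least 2-fold from both other libraries in the SQH library, 37 higher and 28 lower. Ranked by the smaller of their 2 differences, the highest named genes were Adora1 and Mybph, whose reads cannot be told apart, Sv2b, Nrgn and Atf3, and the lowest Mss51, Gadd45g, Sc5d, Kcna5 and Arrdc2. Atf3 stood at 6.78 in the control, 5.98 in the exercise control and 8.72 with SQH, Pdk4 at 11.42, 11.04 and 13.004, and Ppargc1a at 10.75, 11.35 and 12.41. Mss51 stood at 10.95, 12.45 and 9.30. For comparison, 20 genes were higher and 51 lower in the control than in both other libraries, and 75 and 261 in the exercise control. These are not separate observations. Those of the control are the genes counted above as lower and higher in both exercised libraries. Those of the exercise control are the genes counted above as at least 2-fold lower and higher again with SQH. Ccdc36, Kif3a and Timm22 followed the order of Amd1 and Amd2 across the libraries. Ccdc36 stood at 12.62, 10.56 and 9.86, Kif3a at 12.14, 10.32 and 9.56, Timm22 at 12.74, 11.004 and 10.35, Amd1 at 12.60, 11.54 and 10.69, and Amd2 at 12.99, 11.68 and 11.11. Prss22 was listed at 0, 11.11 and 0, and Tecrl at 7.76, 0 and 6.83. These rows were chosen after their values were seen.

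Slow-fibre contractile genes were far lower in the exercise control library than in both others. Scaling of the libraries is argued against, since the list median of exercise control against control was still -3.25 after quantile normalization. Both scalings shifted the median of all tested genes by at most 0.07 in size. Thinning of reads was applied only to the counts of called genes and not to this list. The list median was -3.45 with a prior count of 5 and -3.48 among the genes of highest expression. These values argue against few reads as the source of the low list median. A candidate explanation is that the muscle sampled for that library held fewer slow fibres. This would lower slow genes by a like amount and raise the share of fast ones. The fast-fibre median of 0.42 goes that way. Since the labels do not name the muscle, whether the 3 libraries came from the same one is not known. Nerve and Schwann cell markers were higher in the exercise control library too (median 1.47), and their bearing on sampling was not tested. The slow genes were not all lower by a like amount (-5.69 to -0.29, 10 of 16 within 2-fold of the list median), although Tnni1 (-4.07), Tnnt1 (-4.06), Tpm3 (-4.02) and Myh7 (-3.92) were. The 2-fold bound was set after the values were seen, so it cannot decide, and this explanation stays open. It also remains open whether exercise lowered these genes and SQH largely prevented it: the slow-fibre median of SQH against control was -0.34, and with 1 library per group the design cannot separate treatment from sampling.

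Some single genes were far lower in the exercise control library than in both others, among them Sdhd, at 9.69 in the control, 5.87 in the exercise control and 10.60 with SQH. Fewer mitochondria in that library is argued against for Sdhd, because Sdha (0.06), Sdhb (-0.35) and Sdhc (-0.12), subunits of the same enzyme, had a median difference of -0.12. Sequence differences between outbred animals near the 3' ends might remove a gene's reads in a library, and would be expected in every library. At least 8-fold from both other libraries lay 2 genes in the control, 0 in the SQH library and 22 in the exercise control, of which 9 are in the slow-fibre list. The uneven counts leave the explanation open, and no reads were examined here.

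Over 541 pairs of genes on opposite strands that share exonic bases, the differences of exercise control against control correlated at r = 0.45 (bootstrap 95% interval 0.30 to 0.59), across gene pairs and not replicates. For comparison, 510 convergent pairs within 10 kb that share no exonic base gave r = 0.072 (-0.007 to 0.15). This argues against regulation shared by neighbours of that orientation. The 541 overlapping pairs could have any orientation, and divergent pairs had no such comparison, so regulation shared by those stays open. The values are in line with reads of overlapping genes having been counted for both without regard to strand, a hypothesis that would also account for Mybph with Adora1, and for Rabep2 (0.81) with Atp2a1 (0.72). Other such pairs did not move together, as with Paox (-5.25) and Echs1 (0.04), Fabp3 (-1.11) and Zcchc17 (-0.14), and Phkg1 (0.60) and Sumf2 (0.12). Which gene of such a pair the reads came from is not established by these data.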
